A study of Mus musculus with 6 samples.

How the data were processed

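RNA was sequenced from regulatory T cells (Tregs) sorted out of T11 tumors in 6 libraries, 3 from untreated mice and 3 from mice given anti-PD-1. Per the labels' protocols, tumors were dissociated with enzymes, lymphocytes were enriched on a density gradient, GFP-positive cells were sorted to a purity above 90%, RNA was extracted with a column kit and libraries were made with the NuGEN Ovation SoLo kit. The deposited values are raw counts of fragments per gene, which the authors made with featureCounts 1.5.2 on the UCSC mm10 gene annotation, per the file headers. The command in the header counts read pairs as fragments, assigns them by strand (setting 1) and reads 1 alignment per library whose name contains bbmap. The submitters' processing notes also name bcl2fastq, FastQC and DESeq2. Settings of the aligner, any filter on reads and the handling of duplicate reads are not given in the sources used here.

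The table has 23420 genes named by symbol, with mm10 coordinates. A spreadsheet had turned 27 symbols into dates, and all 27 were resolved by their mm10 position against a RefSeq table of the assembly GRCm38.p6. 1 further column, without a name, holds 6 values and was not used. All 23420 genes entered the library totals. Mitochondrial genes and immunoglobulin or T cell receptor segments were not analysed here. A planned measure of library composition, the share of counts in mitochondrial genes, therefore has no value. Total counts ran from 4766533 to 6686774 per library.

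From these counts, edgeR 4.0.16 in R 4.3.3 was used for the comparison between treatments. Genes passed filterByExpr at its defaults (a count of 10, and 15 in total), which left 10352 genes holding 99.8% of the counts, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit with robust shrinkage, glmQLFTest) was two-sided, with treatment as the only term and Benjamini-Hochberg adjustment over all tested genes at 0.05. CPM values were scaled by TMM, errors are SDs over 3 libraries, and SEs of fold changes come from the same fit. The replicate numbers of the groups do not overlap, so no samples were paired. For every pair of libraries, a chi-square statistic of the counts lay between 9.88 and 32.3 per degree of freedom, so no library was counted as a copy of another.

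Before the data were examined, the tests, the rule for naming genes, 21 gene lists and 12 lists of cell type markers were fixed. The rule names up to 10 genes per direction that passed, with no overlap between groups and a mean of at least 5 CPM, filled to 10 with the genes of smallest unadjusted p. It adds a panel of 21 Treg and checkpoint genes whatever their result, and up to 4 members of each list by smallest p. Genes named beyond this rule, and 7 of the 10 genes drawn as CPM per library, were chosen after their values were seen. Some genes that the rule names are not reported here. Of 662 list entries, 11 matched through a synonym and 11 matched no symbol. A list entered the test with at least 3 tested members, which 29 of the 33 lists had. Lists were compared with all other genes by camera (limma 3.58.1), with a preset correlation of 0.01 between members, two-sided, Benjamini-Hochberg adjusted over the 29 lists. Some lists share members, at most 4 between any pair. For each list, members were also counted after adjustment over the list alone.

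Library composition was compared by the share of counts in ribosomal protein genes, in the 10 highest genes and in each marker list, and by the number of genes detected, with a two-sided exact permutation test over the 6 libraries. Its smallest possible p is 0.1, and 10% of measures separate the groups by chance. The adjustment of its p also took in total counts and the shares of Rn45s and Malat1.

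Alternatives were DESeq2 1.42.0, limma-voom with and without quality weights, other edgeR settings including a test against a 1.5-fold change, other scalings and filters, removal of ribosomal protein genes, camera with an estimated correlation or with ranks, fry, and leaving out each library in turn. The tests were tested on simulated data, counts drawn from the means, dispersions and library sizes of the 10352 genes. For this comparison, edgeR called 9.06% of genes changed 1.5-fold, 33.8% of those changed 2-fold and 71.8% of those changed 4-fold, and 10.5% of its calls were false. DESeq2 called 12.8%, 34.7% and 74.1% of the same genes, with 16.6% of its calls false. Over 5 simulations, 320, 320 and 309 genes were changed 1.5-fold, 2-fold and 4-fold, beside 49218 unchanged ones. The false shares depend on these numbers and sizes, which are not known for the real data. With the Treg identity list lowered by 0.5 (log2) in simulated counts, camera called that list and 2 others, both of which share members with it. The simulated genes were drawn independently of each other. The simulation therefore does not test the preset correlation where members correlate, as in the G2 and mitosis list (estimated correlation 0.403).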

Results

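Tregs were profiled from tumors of T11 cells, a transplanted mouse model of claudin-low triple-negative breast cancer, grown in BALB/c mice whose FoxP3-expressing cells carry GFP. Mice received 10000 tumor cells and were left untreated or were given 200 µg of the anti-PD-1 antibody J43 by 2 intraperitoneal injections per week. Tumors were collected at 150 mm2, and RNA from sorted Tregs was sequenced in 3 untreated libraries (1, 2 and 3) and 3 anti-PD-1 libraries (4, 5 and 6). Total counts were 6686774, 5470816 and 5825110 in the untreated libraries and 5219249, 4766533 and 4836408 in the anti-PD-1 libraries, so every untreated library was deeper than every treated one. A multidimensional scaling used, for each pair of libraries, the genes that differed most between them. Its dimension 1 (35.7% of its variance) set untreated library 1 at 2.40 and the other libraries between -0.67 and -0.39. Dimension 1 thus did not follow treatment. The labels do not say that libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

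The main comparison asked which genes differ between tumor Tregs of anti-PD-1-treated and untreated mice. Klf2, a transcription factor of quiescent and recirculating T cells, rose 3.22-fold after anti-PD-1, from 120 ± 20.4 to 389 ± 66.6 CPM (SD, n = 3 per group). Rhob, a small GTPase induced early after stimulation, rose from 27.4 ± 7.58 to 86.2 ± 25.1 CPM. Jun, a subunit of the AP-1 transcription factor, rose from 123 ± 4.16 to 266 ± 37.3 CPM. In mm10, Klf2 lies on chromosome 8 (72319062 to 72321654, plus strand), Rhob on chromosome 12 (8497759 to 8499985, minus strand) and Jun on chromosome 4 (95049036 to 95052222, minus strand). These 3 were the genes that passed among 10352 tested, and none fell. The log2 fold changes in edgeR's quasi-likelihood test were 1.69 ± 0.17 for Klf2 (SE, Benjamini-Hochberg adjusted p = 1.25e-05), 1.11 ± 0.16 for Jun (adjusted p = 0.0034) and 1.65 ± 0.26 for Rhob (adjusted p = 0.00707). Each of the 3 was higher in all 3 anti-PD-1 libraries than in any untreated library. At an unadjusted p under 0.05 stood 438 genes with higher and 421 with lower values, together 8.3% of those tested. The groups did not overlap in 1410 genes (13.6%, where chance gives 10%).

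**Figure D1:**
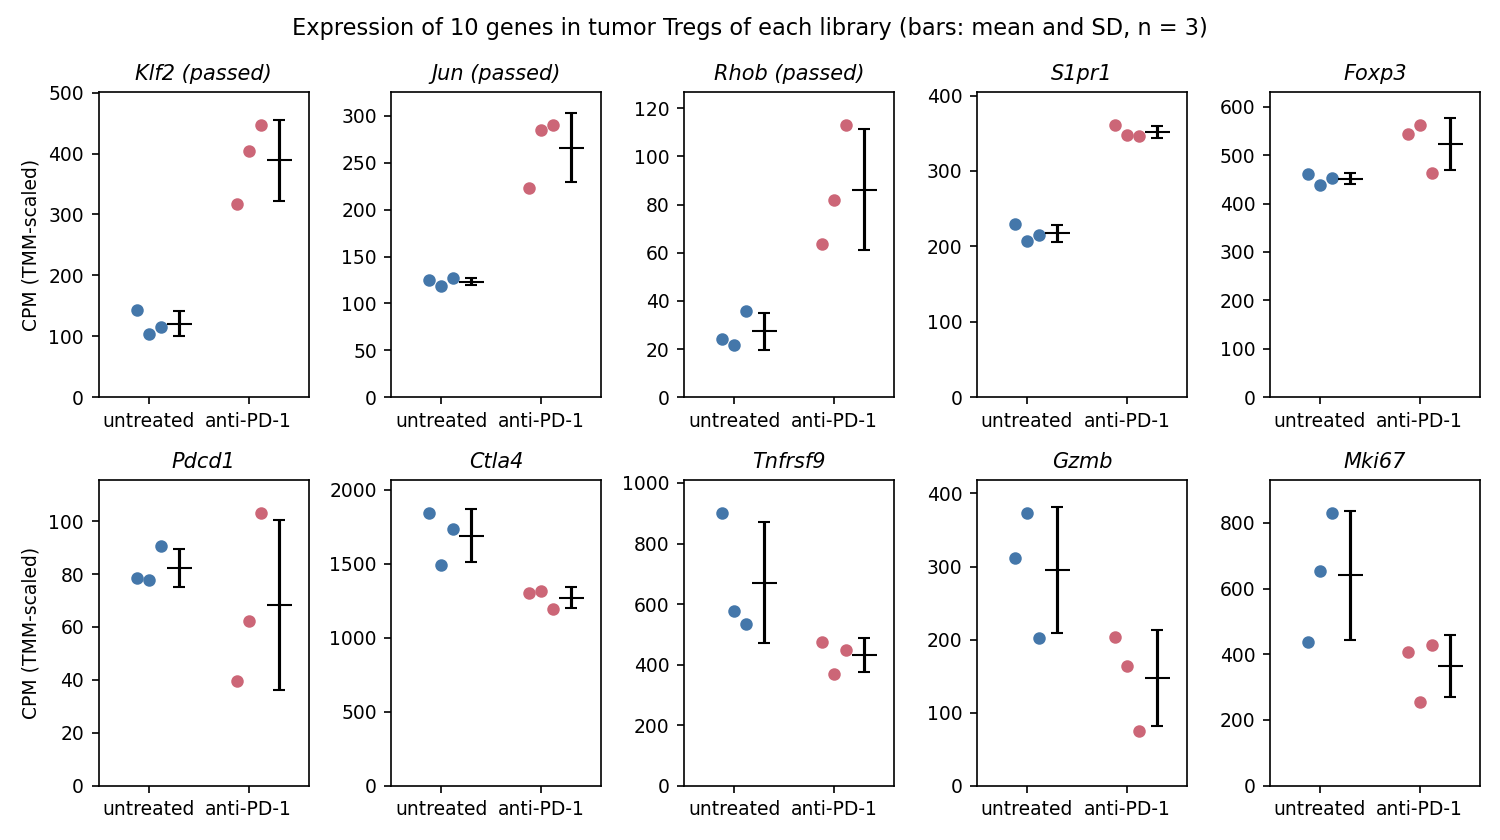
CPM of 10 genes (y axis, TMM-scaled, from 0) in the 3 untreated (blue) and 3 anti-PD-1 (red) libraries, with mean and SD in black. Klf2, Jun and Rhob passed the test over all genes, and for Klf2 the anti-PD-1 mean was 389 CPM against 120 CPM.

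Further genes came close in edgeR without passing. Among those with higher values were Fos, the AP-1 partner of Jun, at a log2 fold change of 0.91 ± 0.18 (SE), and Ier2, another immediate early gene, at 0.92 ± 0.19. S1pr1, the sphingosine-1-phosphate receptor through which lymphocytes leave tissue, stood at 217.5 ± 11.4 CPM untreated and 352 ± 8.40 CPM after anti-PD-1. Klf3 and the glucocorticoid-induced gene Tsc22d3 had log2 fold changes of 1.19 and 0.91. Among those with lower values were the GTPase gene Arl5a (-0.69 ± 0.14) and Sypl (-0.92 ± 0.19). EdgeR's adjusted p for these 7 genes lay between 0.0658 and 0.0971. Below them came Ltf (-2.53 ± 0.58), the integrin gene Itgb8 (-0.74 ± 0.17), whose product activates TGF-beta, Gcnt1 (-0.98), the condensin gene Ncapg2 (-1.03), Rgs9 (-1.23), the inhibitory receptor gene Klrg1 (-0.84) and Alms1 (-0.99), with edgeR adjusted p from 0.136 to 0.239. In none of the genes of this paragraph did the groups overlap, which was a condition for naming them. DESeq2 called 34 genes (21 higher, 13 lower), among them all 3 that edgeR called and 12 of the 14 genes of this paragraph, all but Ltf and Rgs9 (DESeq2 adjusted p from 0.000221 for Arl5a to 0.0427 for Ncapg2). Ltf and Rgs9 were among 6021 genes to which DESeq2 gave no adjusted p. Its adjustment therefore ran over fewer genes than edgeR's. Leaving out 1 library moved edgeR's count from 3 to 19 (without untreated 1), 6 (without untreated 2), 5 (without untreated 3 or anti-PD-1 6) or 1 (without anti-PD-1 5). Klf2 passed in every one of 20 alternatives. Jun missed the threshold without anti-PD-1 5 (edgeR adjusted p = 0.0539, range over its alternatives 1.11e-07 to 1), and Rhob did so without untreated 2 (0.0571), anti-PD-1 5 (0.0539) or anti-PD-1 6 (0.124; range 3.76e-07 to 0.247).

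Of the 21 panel genes of Treg identity, checkpoints and effector function, none passed edgeR's test over all genes, 17 had a fold change below 0, and 8 had an unadjusted p under 0.05. DESeq2 and limma-voom with quality weights called Mki67 (adjusted p = 0.0382 and 0.027, range over its alternatives 0.000165 to 1), and without a filter edgeR also called Mki67, Tnfrsf9 and Gzmb. The target of the antibody, Pdcd1, stood at 82.3 ± 7.17 CPM in untreated and 68.3 ± 32.2 CPM in anti-PD-1 libraries, and its ligand genes Cd274 and Pdcd1lg2 at log2 fold changes of -0.01 ± 0.17 and 0.03 ± 0.32. Foxp3, the lineage factor by which the cells were sorted, stood at 451 ± 11.6 and 523 ± 53.6 CPM, a log2 fold change of 0.21 with a 95% interval from -0.08 to 0.51. Values below 0 with an unadjusted p under 0.05 were those of the co-inhibitory receptor Ctla4 (-0.41 ± 0.13), the IL-2 receptor chain Il2ra (-0.35 ± 0.16), Icos (-0.35 ± 0.14), 4-1BB (Tnfrsf9, -0.64 ± 0.17), Tigit (-0.49 ± 0.21), the cytokine Il10 (-0.69 ± 0.32), the protease Gzmb (-0.998 ± 0.34) and the proliferation marker Mki67 (-0.82 ± 0.22). Gzmb stood at 296 ± 86.3 CPM untreated and 147 ± 65.4 CPM after anti-PD-1, and Mki67 at 641 ± 196 and 363 ± 94.1 CPM. The other fold changes were -0.24 for Ikzf2, -0.06 for Tnfrsf18, 0.07 for Tnfrsf4, -0.20 for Ccr8, -0.69 for Lag3, -0.41 for Havcr2, 0.05 for Tgfb1, -0.48 for Ifng and -0.45 for Tbx21. EdgeR's adjusted p over the panel ran from 0.312 to 0.990, and the sign of Pdcd1 turned without anti-PD-1 library 4 (0.0067).

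The gene lists asked whether genes of a shared function moved together. Genes of resting, lymphoid-homing T cells were higher after anti-PD-1, with 16 of 17 tested members above 0, the exception being Ly6c1 (-0.51 ± 0.56), and a median log2 fold change of 0.69. Camera gave this list an adjusted p of 1.47e-15 at the preset correlation, and adjusted p = 0.237 with an estimated correlation. Klf2 rose over all genes, and 9 members were higher when adjusted over the list alone. They included S1pr1, Klf3 at 29.1 ± 5.93 CPM untreated and 66.7 ± 13.7 CPM after anti-PD-1, and the quiescence factor Foxp1 at 134 ± 5.22 and 200.3 ± 50.01 CPM. Every anti-PD-1 library had a higher mean level of the list than every untreated library. In all, 8 of 29 lists passed with the preset correlation, 4 higher and 4 lower. None passed with the correlation estimated from these libraries, where 3 lists had an unadjusted p under 0.05, and 1 passed fry. Every other split of the 6 libraries into groups of 3 also called lists at the preset correlation, from 2 to 8.

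**Figure D2:**
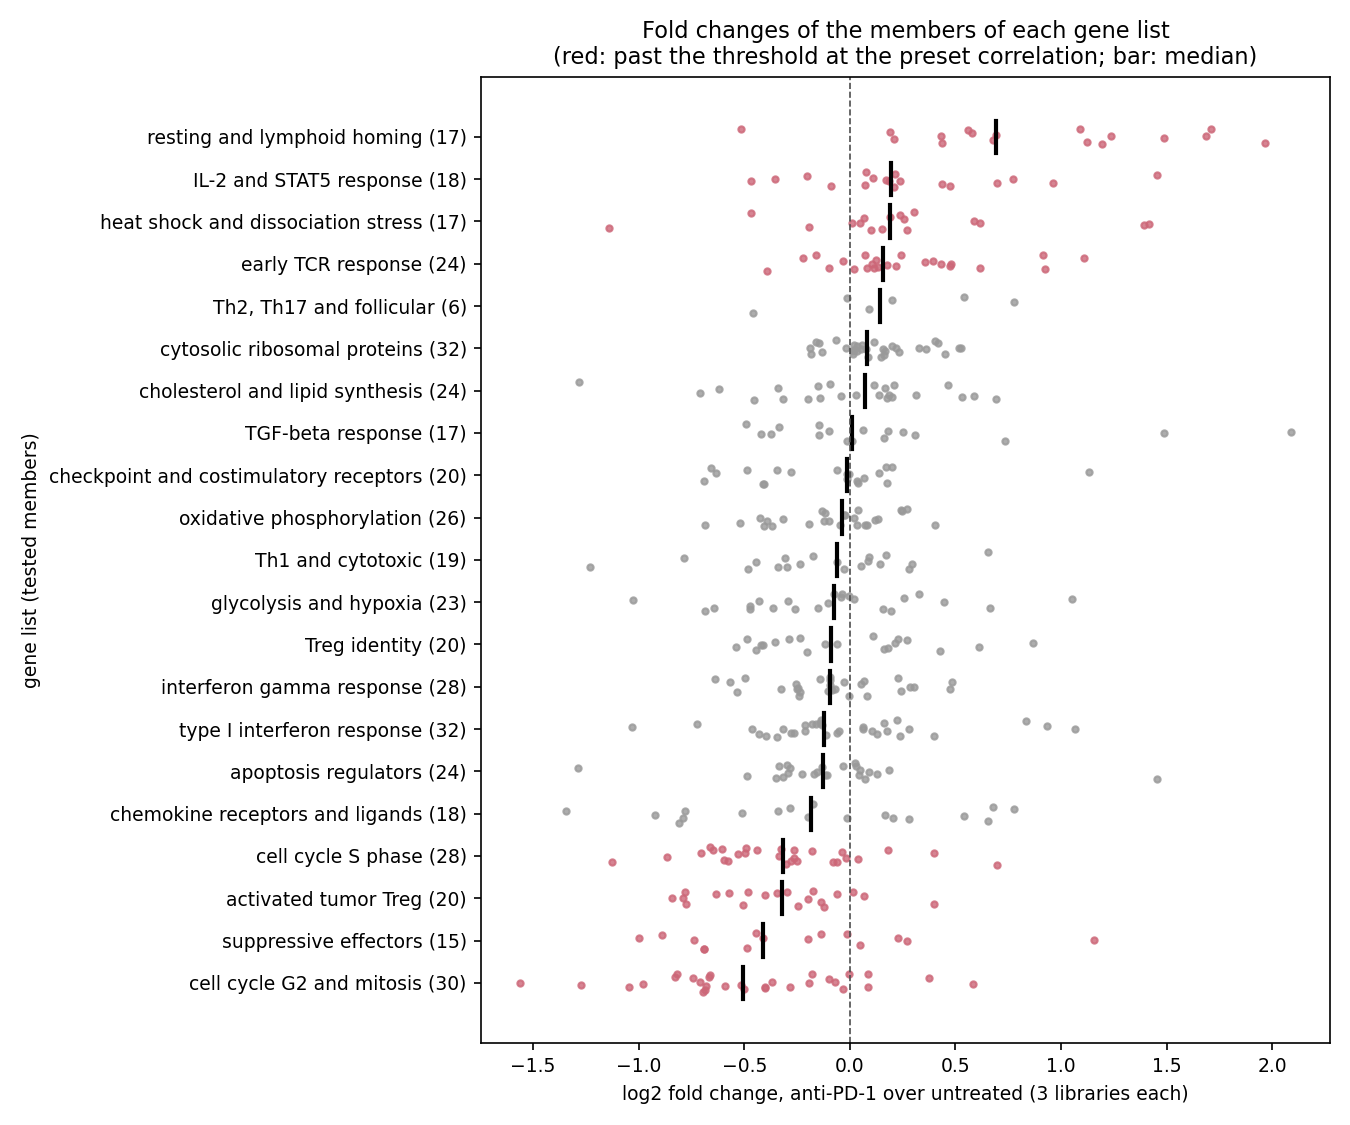
Log2 fold change of each tested member (x axis, points) in the 21 gene lists (y axis, number of tested members in brackets), with the median as a black bar. Red lists passed camera with the preset correlation; the resting and lymphoid homing list has the highest median, 0.69, and the G2 and mitosis list the lowest, -0.51.

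Genes of activated tumor Tregs and of suppressive function were lower after anti-PD-1. In the activated tumor Treg list, 17 of 20 tested members lay below 0 (not Traf1, Tnfrsf4 and Irf4), with a median of -0.32 (camera adjusted p = 1.4e-06, and adjusted p = 0.237 with an estimated correlation). None passed over all genes by edgeR, where DESeq2 called Klrg1 (adjusted p = 0.0262) and Ccr2 (0.0427). In edgeR, 5 were lower when adjusted over the list alone, namely Klrg1, Tnfrsf9, the chemokine receptor Ccr2 and the transcription factors Maf and Prdm1 (-0.48 ± 0.18). Ccr2 stood at 652 ± 72.4 CPM untreated and 376 ± 132 CPM after anti-PD-1, and Maf at 529 ± 33.3 and 373 ± 63.9 CPM. In the suppressive effector list, 11 of 15 tested members lay below 0 (not Prf1, Nt5e, Lrrc32 and Tgfb1), with a median of -0.41 (camera adjusted p = 0.00116, and adjusted p = 0.237 with an estimated correlation). None passed over all genes by edgeR, where DESeq2 called Itgb8 (adjusted p = 0.00946). In edgeR, 6 were lower when adjusted over the list alone, among them Itgb8, the prothrombinase-like immunoregulator Fgl2 (-0.49 ± 0.15), Ctla4 and the enkephalin precursor Penk (-0.89 ± 0.31). Fry called this list (adjusted p = 0.0318), and camera with ranks did not (adjusted p = 0.064, range over its alternatives 0.000948 to 0.237). The median of the activated list was -0.209 without untreated library 2. In both lists, the mean level of every anti-PD-1 library lay below that of every untreated library.

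Cell cycle genes were lower as well. In the G2 and mitosis list, 26 of 30 tested members lay below 0, with a median of -0.51 (camera adjusted p = 3.42e-09, and adjusted p = 0.409 with an estimated correlation). None passed over all genes by edgeR, where DESeq2 called Mki67 (adjusted p = 0.0382) as did limma-voom with quality weights (0.027, range over its alternatives 0.000165 to 1). In edgeR, 11 were lower when adjusted over the list alone, among them Mki67, the kinetochore gene Ndc80 (-1.56 ± 0.42), the topoisomerase Top2a (-0.50 ± 0.16) and Cenpf (-0.66 ± 0.22). In the S phase list, 24 of 28 tested members lay below 0, with a median of -0.32 (camera adjusted p = 0.000423, and adjusted p = 0.582 with an estimated correlation). None of them passed edgeR's test over all genes or adjusted over the list alone, and the smallest p belonged to the ribonucleotide reductase genes Rrm1 (-0.59 ± 0.19) and Rrm2 (-0.70 ± 0.27) and to Pola1 (-0.58 ± 0.21). The S phase median was -0.497 without untreated library 1, -0.18 without anti-PD-1 library 5 and -0.562 without anti-PD-1 library 6. The mean levels of both cell cycle lists overlapped between the groups, with anti-PD-1 library 6 at 0.18 and untreated library 1 at -0.09 in the G2 and mitosis list.

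**Figure D3:**
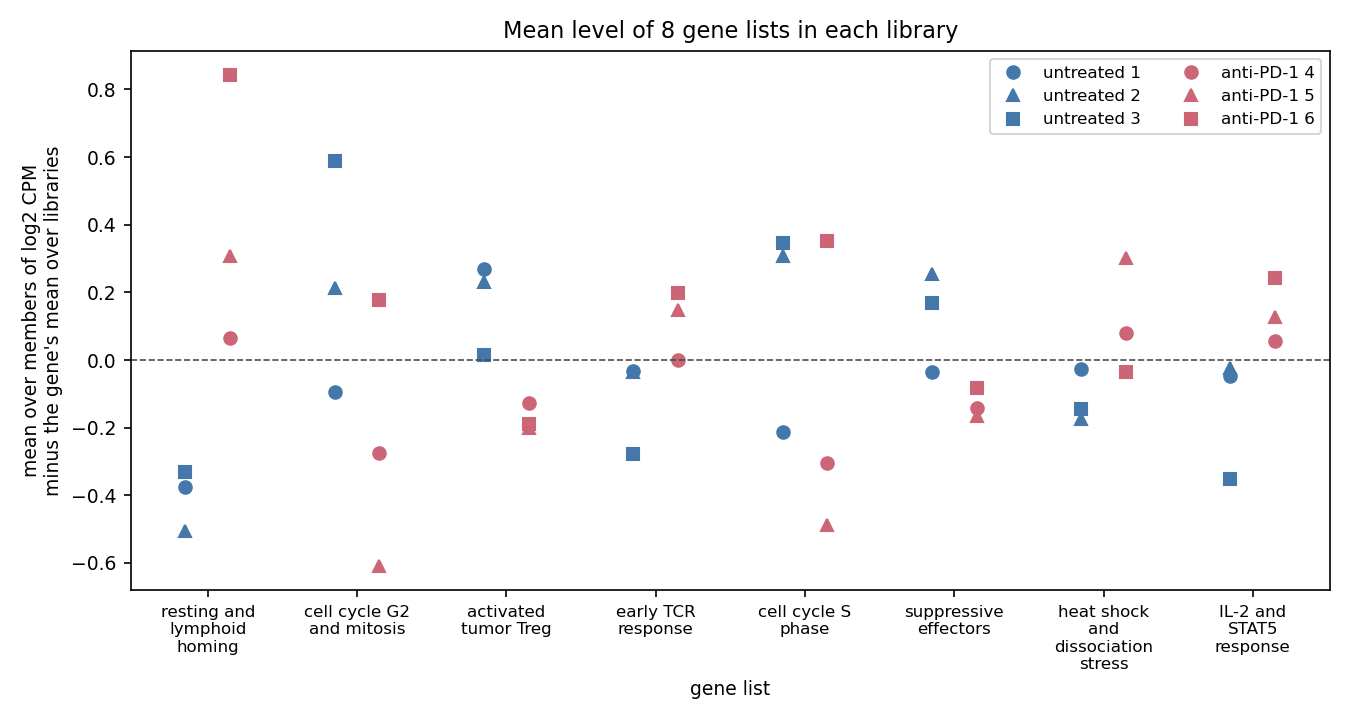
Mean level of the 8 lists that passed camera with the preset correlation (y axis, mean over members of log2 CPM minus the gene's mean over the 6 libraries) in each untreated (blue) and anti-PD-1 (red) library. The resting and lymphoid homing list is lowest at -0.51 (untreated 2) and highest at 0.84 (anti-PD-1 6), and the groups overlap in the cell cycle and heat shock lists.

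Immediate early, heat shock and IL-2 response genes were higher. In the early TCR response list, 19 of 24 members lay above 0 (not Fosl2, Myc, Nr4a2, Egr3 and Tnfaip3), with a median of 0.16. Camera's adjusted p was 9.95e-06, and 0.386 with an estimated correlation. Jun rose over all genes, and 5 members were higher when adjusted over the list alone, namely Jun, Fos, Ier2, the antiproliferative gene Btg2 (0.48 ± 0.14) and the phosphatase gene Dusp5 (0.47 ± 0.17). In the heat shock and dissociation stress list, 14 of 17 tested members lay above 0, with a median of 0.19 (camera adjusted p = 0.00894, and adjusted p = 0.409 with an estimated correlation). None passed over all genes by edgeR, where DESeq2 called Hspa1a (adjusted p = 0.000109). In edgeR, 4 were higher when adjusted over the list alone: Dnajb1 (0.59 ± 0.18), Hsph1 (0.62 ± 0.19) and the near-identical neighbours Hspa1a (1.39 ± 0.30) and Hspa1b (1.42 ± 0.38), whose separate counts are uncertain. In the IL-2 and STAT5 response list, 14 of 18 members lay above 0 (not Nfil3, Il2ra, Socs2 and Pim2), with a median of 0.20. Camera's adjusted p for it was 0.00902, and 0.436 with an estimated correlation. At an unadjusted p under 0.05 in edgeR, 4 members were higher and 2 lower, Nfil3 (-0.47 ± 0.19) and Il2ra (-0.35 ± 0.16). None passed over all genes by edgeR, where DESeq2 called Bcl2 (adjusted p = 0.0127) and Socs3 (0.0317). In edgeR, 4 were higher when adjusted over the list alone: the survival factor Bcl2, the cytokine signalling inhibitor Socs3 (0.96 ± 0.23), Ccnd3 (0.77 ± 0.26) and Il4ra (0.44 ± 0.16). Bcl2 stood at 20.4 ± 2.68 CPM untreated and 56.3 ± 31.2 CPM after anti-PD-1. Camera's adjusted p for the heat shock list was 0.0663 without anti-PD-1 library 5 and 0.105 with ranks (range over its alternatives 2.58e-05 to 0.409), and for the IL-2 list 0.43 without untreated library 3, 0.0503 without anti-PD-1 library 6 and 0.064 with ranks (range 0.0025 to 0.436). Without untreated library 3, the medians were 0.0598 for early TCR, 0.0449 for heat shock and 0.0793 for IL-2 genes. The others that moved over 1.5 times were early TCR without untreated 1 (0.257), untreated 2 (0.251) or anti-PD-1 5 (0.234), heat shock without anti-PD-1 5 (0.109) and IL-2 without untreated 2 (0.299).

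The remaining 13 gene lists did not pass camera, and no member of them passed edgeR's test over all genes, while DESeq2's calls included Bcl2 and Ccr2. Chemokine receptors and ligands had a median of -0.19 (camera adjusted p = 0.128), and 3 members were lower when adjusted over the list alone, including Ccr2 and Ccr3 (-0.92 ± 0.29). Checkpoint and costimulatory receptors had a median of -0.01 (adjusted p = 0.18), with Tnfrsf9 lower when adjusted over the list alone, and Treg identity genes a median of -0.09 (adjusted p = 0.452), with none. Among apoptosis regulators (median -0.13, adjusted p = 0.414), Bcl2 was higher when adjusted over the list alone. In the TGF-beta response list (median 0.01, adjusted p = 0.914), 2 were higher when adjusted over the list alone, the inhibitor Id3 (1.49 ± 0.49) and Gpr34, and 2 were lower, the integrin Itgae (-0.42 ± 0.15) and Id2 (-0.49 ± 0.18). In the following lists no member passed when adjusted over the list alone. Interferon gamma response genes had a median of -0.09 (adjusted p = 0.181), with Gbp5 at -0.64 ± 0.18, and type I interferon response genes a median of -0.12 (adjusted p = 0.414), with Rtp4 at -0.72 ± 0.30. Th1 and cytotoxic genes had a median of -0.06 (adjusted p = 0.801), with Cxcr3 at 0.66 ± 0.25, and Th2, Th17 and follicular genes a median of 0.14 (adjusted p = 0.801), with Ahr at -0.46 ± 0.18. Glycolysis and hypoxia genes had a median of -0.08 (adjusted p = 0.185), with Bnip3 at -1.03 ± 0.32 and Hif1a at -0.36 ± 0.14, and oxidative phosphorylation genes a median of -0.04 (adjusted p = 0.414). Cytosolic ribosomal protein genes had a median of 0.08 (adjusted p = 0.181). Cholesterol and lipid synthesis genes had a median of 0.07 but a mean of -0.02, and camera placed the list lower (adjusted p = 0.937), with Fasn at 0.59 ± 0.20. Leaving out 1 library brought 4 of these lists past camera's threshold. Interferon gamma genes passed without untreated library 1 (median -0.193, adjusted p = 0.00263) and anti-PD-1 library 5 (-0.221, 0.00129; range over its alternatives 0.00129 to 0.817), type I interferon genes without anti-PD-1 library 5 (-0.192, 0.00131; range 0.00131 to 0.974), glycolysis genes without untreated library 1 (-0.18, 0.0137; range 0.0137 to 0.732) and ribosomal protein genes without untreated library 3 (0.231, 0.0111), anti-PD-1 library 4 (0.187, 0.0107) or anti-PD-1 library 5 (0.245, 0.00104; range 0.00104 to 0.928).

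The last comparison asked whether other cells or RNA quality moved with treatment. Markers of other cells were scarce in all libraries: macrophage and monocyte markers took 0.0428% ± 0.00335 of counts in untreated and 0.0401% ± 0.00281 in anti-PD-1 libraries (SD, n = 3 per group), and CD8 T cell markers 0.00309% ± 0.00155 and 0.00415% ± 0.00207. The CD8 chain gene Cd8a stood at 9.35 and 15.4 CPM, the tumor and fibroblast gene Fn1 at 33.3 and 38.6 CPM, and the myeloid lysozyme Lyz2 at 2.41 and 3.80 CPM, against 423 and 478 CPM for Cd4. T cell markers took 0.357% ± 0.0502 and 0.374% ± 0.00719 of counts, neutrophil markers 0.00133% and 0.00194%, dendritic cell markers 0.0117% and 0.0122%, NK and innate lymphocyte markers 0.00536% and 0.00586%, and B and plasma cell markers 0.0023% and 0.00244%. Fibroblast and tumor markers took 0.00837% and 0.00927%, epithelial markers 0.00228% and 0.00193%, mast cell and basophil markers 0.00127% and 0.00179%, and erythroid and platelet markers 0.00034% and 0.000401%. Endothelial markers were the 1 set that separated the groups, at 0.00701% ± 0.000437 and 0.0101% ± 0.00211 (exact permutation p = 0.1, the smallest possible; Benjamini-Hochberg adjusted 0.9), carried by Pecam1 (0.48 ± 0.20), an adhesion gene that T cells also express. The ribosomal RNA precursor Rn45s took 22.1% ± 0.178 and 22.8% ± 2.06 of counts, ribosomal protein genes 1.07% ± 0.209 and 1.19% ± 0.299, and the 10 highest genes 28.5% ± 0.46 and 29.0% ± 1.34, and 12060 ± 493 and 12428 ± 666 genes were detected; none of these separated the groups.

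Of the 12 marker lists, 8 had enough tested members for camera and none passed. Their medians were -0.000043 for T cells (mean 0.07, placed higher), 0.32 for CD8 T cells, -0.63 for NK and innate lymphocytes, 0.03 for macrophages and monocytes (placed lower), 0.04 for dendritic cells (placed lower), 0.51 for B and plasma cells, 0.20 for fibroblasts and tumor cells and -1.28 for epithelial cells, with camera adjusted p from 0.181 to 0.964. No marker gene passed edgeR's test over all genes, and Pecam1 was the 1 marker higher when adjusted over the list alone, as the single tested member of its list. Endothelial, mast cell and basophil, neutrophil, and erythroid and platelet lists had 1, 1, 2 and 0 tested members. Without 1 library, between 1 and 4 of the composition measures other than total counts separated the groups. There were 4 without untreated library 1 or anti-PD-1 library 6 and 2 without untreated library 2. With fewer libraries, chance separates a larger share of measures than the 10% given for all 6.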

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

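Thinning all libraries to the smallest total, removing Rn45s, Malat1, Rmrp and Lars2, and testing lists without ribosomal protein genes were chosen after seeing the data. Klf2 passed under all 20 of its alternatives (1.58 to 1.83). The 3 genes called by edgeR (3 higher, 0 lower) became 34 with DESeq2 (21 higher, 13 lower), 5 with limma-voom (4 and 1), 12 with quality weights (8 and 4), 5 without robust shrinkage, 5 with upper-quartile scaling, 7 with library size only (6 and 1), 52 with no filter (36 and 16) and 6 without ribosomal protein genes (5 and 1), and the cause was not tested. With glmTreat it was 1, by a stricter null of a 1.5-fold change. Without 1 library it ran from 1 (without anti-PD-1 5) to 19 (without untreated 1). DESeq2 gave no adjusted p to 6021 of the 10352 genes, so its adjustment ran over fewer genes than edgeR's. The 8 lists stayed 8 under 3 other scalings, 2 other filters and thinning, and became 5 with ranks (without suppressive effectors, IL-2 and heat shock), 1 with fry and 0 with an estimated correlation, and the cause was not tested. Leaving out 1 library gave 7 to 10 lists, newly including ribosomal proteins in 3 fits, interferon gamma in 2, and glycolysis and type I interferon in 1 each. The single composition measure that separated the groups, total counts left aside, stayed 1 over the filtered genes. It became 1 to 4 measures without 1 library, where chance separates a larger share than with all libraries. Some medians and fold changes changed sign, and the cause was not tested: with DESeq2 size factors, TGF-beta response -0.00168; with upper quartile, Cd274 0.0185, checkpoint receptors 0.0212, oxidative phosphorylation 0.000468 and T cell 0.0312; with library size only, Cd274 0.00871, checkpoint receptors 0.0122 and T cell 0.0229; with no filter, macrophage -0.0713, dendritic cell -0.0278 and B cell -0.00413 (from 0.508); with the strict filter, Th1 0.0663, T cell 0.0117 and dendritic cell -0.0754; with thinning, cholesterol -0.00681, macrophage -0.0153 and dendritic cell -0.0605; without the 4 abundant genes, T cell 4.48e-05. Without 1 library, the ranges that crossed 0 or left the sign reported were Pdcd1 -0.7 to 0.0067, Cd274 -0.113 to 0.12, Pdcd1lg2 -0.26 to 0.288, Tnfrsf18 -0.146 to 0.0892, Tgfb1 -0.0222 to 0.162 and Tbx21 -0.853 to 0.0992. Ranges that kept their sign but moved over 1.5 times were Tnfrsf9 -0.776 to -0.365, Tigit -0.738 to -0.316, Il10 -0.981 to -0.451, Il2ra -0.518 to -0.202, Icos -0.417 to -0.228, Ccr8 -0.555 to -0.0108, Lag3 -1.23 to -0.0738, Havcr2 -0.585 to -0.167, Ifng -0.778 to -0.335, Tnfrsf4 0.0144 to 0.162, interferon gamma -0.221 to -0.0337, apoptosis -0.195 to -0.0751 and NK cell -0.936 to -0.173. For lists, those that crossed 0 were Treg identity -0.0991 to 0.0653, checkpoint receptors -0.129 to 0.00931, chemokine receptors -0.186 to 0.0288, Th1 -0.18 to 0.0372, Th2, Th17 and follicular -0.12 to 0.585, type I interferon -0.192 to 0.112, glycolysis -0.18 to 0.0571, oxidative phosphorylation -0.2 to 0.0424, cholesterol -0.0692 to 0.102, TGF-beta -0.0349 to 0.114 and ribosomal proteins -0.132 to 0.245. For markers, those that crossed 0 or left the sign reported were T cell 0.0107 to 0.088, CD8 -0.0205 to 0.71, B cell -0.389 to 0.956, macrophage -0.152 to 0.311, dendritic cell -0.476 to 0.0986 and fibroblast -0.0858 to 0.327. The 8 called lists kept their sign under every alternative run. At this depth and spread, edgeR called 33.8% of simulated 2-fold and 9.06% of 1.5-fold changes.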

Other observations

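DESeq2 called 31 genes that edgeR did not, of which those below were picked after their values were seen. Txnip, a glucose-sensitive inhibitor of thioredoxin, had a log2 fold change of 0.86 ± 0.24 (SE, DESeq2 adjusted p = 0.0469), the kinase gene Hipk2 0.89 ± 0.25 (0.0493) and the MAP kinase phosphatase gene Dusp10 0.70 ± 0.19 (0.0442). Lower were the cohesin gene Rad21 at -0.53 ± 0.15 (DESeq2 adjusted p = 0.0493) and the translation initiation factor Eif1a at -0.75 ± 0.21 (0.0493). EdgeR's adjusted p for these 5 genes lay between 0.175 and 0.365. The groups did not overlap in 33 of the 34 genes that DESeq2 called, the exception being Txnip. In simulated data, 16.6% of DESeq2's calls were false. That share depends on the number and size of the simulated changes and is not the error rate of these 34 calls.

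Chosen only after the results were seen were the tests of dissociation genes, of T cell receptor target genes, of the Foxp3 bound and of the correlation among cell cycle genes. The early TCR and heat shock lists were higher after anti-PD-1 at the preset correlation (camera adjusted p = 0.386 and 0.409 with an estimated correlation), as tissue digestion or receptor signalling could also make them. Genes known to rise in tissue digestion, outside both lists, had a median at percentile 56.71 of matched random lists; a first version of this list had lain at percentile 86.21 before 3 genes whose values were already known were taken out. T cell receptor target genes had a median of 0.0189, at percentile 75.51, with 6 of 10 above 0 and 4 below. None of them had an unadjusted p under 0.05 in edgeR. Because 7 of the 10 are themselves on the early TCR list, that test is not independent of the list. Neither test decides. At the preset correlation, both lists stayed past the threshold in 5 of the 6 fits without a single library, the heat shock list losing its call without anti-PD-1 library 5 (camera adjusted p = 0.0663, range over its alternatives 2.58e-05 to 0.409; median 0.109), so a single library may carry that part. Without untreated library 3, both medians moved further, to 0.0449 for heat shock and 0.0598 for early TCR genes, with both calls kept (camera adjusted p = 0.0386 each), and the early TCR median was 0.257 without untreated 1 and 0.251 without untreated 2.

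The resting list was higher and the activated and suppressive Treg lists were lower after anti-PD-1 at the preset correlation, and camera called none of the 3 with an estimated one (adjusted p = 0.237 for each). A lower share of Tregs among the sorted cells, as the whole cause, was tested by Foxp3, whose log2 fold change had a lower 95% bound of -0.0779, above the median of -0.321 of the activated list. At the stated sort purity above 90%, Foxp3 had little room to fall that far, so this test cannot decide. Its rule also rests on a single gene and was written after these values had been seen. Other Treg identity genes went both ways at an unadjusted p under 0.05 in edgeR, 6 of 20 lower (Ctla4 -0.41, Swap70 -0.54, Itgae -0.42, Entpd1 -0.44, Tigit -0.49 and Il2ra -0.35, each at least as low as the activated median) and 3 higher (Nrp1 0.43, Gpr83 0.87 and Folr4 0.61), with a list median of -0.09. Gene length or expression level bias is argued against, since 0 of the 3 medians lay inside the middle 95% of matched random lists. Without untreated library 1, which stood apart, the resting, activated and suppressive medians were 0.88, -0.256 and -0.346. Their direction thus did not rest on that library alone. All 3 of 3 lists stayed past the threshold without it at the preset correlation, but other splits of the libraries also passed lists there. Without anti-PD-1 library 6, the resting median was 0.515. The treatment, the share of Tregs and differences between libraries, whether of tumors or technical, stay open and were not tested apart. Camera did not call the suppressive list with ranks (adjusted p = 0.064, range over its alternatives 0.000948 to 0.237).

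The cell cycle lists were lower after anti-PD-1 at the preset correlation, but not with an estimated one (camera adjusted p = 0.409 for G2 and mitosis and 0.582 for S phase). At the preset correlation, both stayed past the threshold in 6 of 6 fits without a single library, with S phase medians of -0.497 without untreated 1, -0.18 without anti-PD-1 5 and -0.562 without anti-PD-1 6. The labels do not tie the libraries of a group to separate mice. A spread in the share of cycling cells between these libraries may explain both lists, since members correlated within groups (0.316 in the S phase and 0.403 in the G2 and mitosis list, against the preset 0.01) and library means overlapped. These values had been seen when that test was written, in place of a first version on the lower adjusted p with an estimated correlation (0.409), so they are compatible with the explanation and no evidence for it.

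The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split called 3 genes, as many as in 1 of the 10 splits, itself, and the highest of the others was 0. For lists at the preset correlation, the real split called 8, 2 of the 10 splits gave as many, itself included, and the highest of the others was 8 (untreated 1 with anti-PD-1 4 and 5 against the rest). Every other split called lists too, and the lowest count was 2 (untreated 1 and 3 with anti-PD-1 5 against the rest). Passing at the preset correlation therefore does not by itself set the real grouping apart. With an estimated correlation, the real split called 0 lists, with 3 at an unadjusted p under 0.05 by camera and fry called 1, as many as the highest of the other splits (untreated 1 with anti-PD-1 4 and 6 against the rest).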
